A study of Homo sapiens with 8 samples.

How the data were processed

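Gene expression was measured on 8 two-colour Agilent arrays of human cell lines. Per the labels, the Cy5 (red) channel held RNA of siRNA-treated or knockout cells and the Cy3 (green) channel held RNA of mock cells of the same line, on every array, so that no array carried the dyes the other way round. The labels give siRNA transfection with Lipofectamine RNAiMAX, gene editing with the Alt-R CRISPR-Cas9 system, RNA extraction with Trizol and a two-colour amplification and labelling kit for small RNA inputs. They give the mock cells as not transfected.

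Per the file headers, the scanner files were made with Feature Extraction 12.1.1.1 and hold spot and local background medians and processed signals as intensity on a linear scale. The deposited matrix of the series holds log10 ratios of Cy5 over Cy3. These equal the log10 ratios that the authors' scanner software wrote, with 0 values differing. The processed signals gave the ratios other than 0 to a tolerance of 0.001. Each array had 62976 features, of which 2075 were controls, and the remaining spots held 58201 probes. A gene name was found for 31104 probes by matching their accessions to a RefSeq gene table, which gave 22439 genes, 6754 of them with several probes; the other 27097 probes had no gene name and were looked at separately. All arrays came from 1 slide and 1 scan by the headers. Genome positions are not given because the array headers and the gene table refer to different genome builds.

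Median spot signals were taken with their local background medians in R 4.3.3 with limma 3.58.1. Background was corrected by the normexp method with an offset of 50, which draws the log2 ratios of dim genes toward 0, and dye bias was removed by loess within each array with control spots given no weight. Spots that the scanner software marked as outliers, 104 to 173 per array, were left out, and no spot was saturated. Spots of a probe were averaged, and each gene was represented by its brightest probe. A gene was tested in a comparison if its probe was well above background in at least 1 channel on every array of that comparison. How many genes could be tested thus depended on signal over background, and the number of arrays limits the precision.

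The reagent, meaning an siRNA or a knockout line, was taken as the replicate, and the 2 arrays of siHMGA2-2 and of knockout #8 were averaged. The 6 reagents formed 3 groups of 2 and were fitted together with lmFit and eBayes, with 3 residual and 1.72 prior degrees of freedom. The log2 ratio of treated over mock was tested against 0 by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment within each comparison. The comparisons were siHMGA2, HMGA2 knockout, the mean of both, their difference, and siSERPINH1. A gene passed at an adjusted p under 0.05, and for the mean of both methods it also needed 1 sign on all 6 TE-8 arrays. SE values are those of the fit. Nothing in the labels says that arrays of a group come from separate cultures, so the p-values measure only the spread between these samples. The test against 0 also leaves out the spread of the mock RNA, which the 2 reagents of each group share. A deviation of a mock RNA thus counts as a change common to both reagents. Without an array of swapped dyes, a gene-specific dye effect would be part of each ratio and would cancel only in the difference of the 2 methods.

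Codes in the deposited array names assigned 2 shared mock RNAs, here called mock A and mock B, to the TE-8 arrays. The labels do not state this, and the Cy3 signals were compared under this grouping. Across 22459 probes, Cy3 signals of TE-8 arrays with the same mock correlated with r from 0.994 to 0.996. For TE-8 arrays with different mocks r was from 0.981 to 0.984. The codes also assigned 1 treated RNA to both siHMGA2-2 arrays and 1 to both knockout #8 arrays. Cy5 signals of these pairs correlated with r 0.998 and 0.992, against at most 0.961 for other TE-8 pairs. Both MKN45 arrays held a further mock RNA, mock C. The correlation of unchanged groups on these mocks was simulated 100 times, with the unchanged cells set midway between mock A and mock B.

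The gene lists held mesenchymal and EMT genes, epithelial junction genes, collagens and extracellular matrix, collagen processing enzymes and chaperones, the unfolded protein response, cytosolic heat shock genes, the type I interferon response, G2/M genes, DNA replication genes, p53 target genes, squamous differentiation genes, squamous basal and lineage markers, gastric and intestinal lineage markers, genes reported downstream of HMGA2, TGF-beta and YAP response genes, NF-kB and inflammatory cytokine genes, sterol synthesis genes, hypoxia and glycolysis genes, and RNA interference machinery. These 19 lists were tested against all other tested genes with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

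The genes named are the targeted gene, the 8 passing genes with the largest mean rise and the 8 with the largest mean fall among those of 1 sign on every array, and members of each list: up to 2 passing members a side, up to 4 where the list itself passed, and otherwise the member of smallest p. Where fewer than 8 genes passed on a side, the genes of smallest p took the free places and are said not to pass. For the difference of the methods, 5 genes a side are named. A few genes that this rule picks are not reported here. Groups, comparisons, tests, gene lists, this naming rule and the alternative settings named next were fixed before the data were examined.

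The alternative settings changed the background correction, dye normalization, offset, filter on dim probes, prior, probes per gene, unit of replication, arrays in the fit, threshold and set test, used the deposited log10 ratios, subtracted the arrays of the other cell line, and left out each array and each reagent. The alternatives chosen after the data were seen are described with their effect in the closing section. The procedure was tested on simulated data whose spread between reagents was drawn from the fitted prior. Genes and reagents were independent, all groups had like spread, and no mock RNA was shared. The counts therefore do not give the error rate on the real arrays. With 100 genes changed in each size class among 14959, the fit called 53 at a log2 size of 1 and 84 at a log2 size of 2, with 9 false calls, and called 0 genes in the unchanged knockout and siSERPINH1 groups.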

Results

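Transcript levels were compared on 8 two-colour arrays, each with RNA of treated cells against RNA of mock cells of the same line. TE-8, an esophageal cancer line, received siRNA against HMGA2 on 3 arrays, with siHMGA2-2 on 2 arrays and siHMGA2-3 on 1. TE-8 lines with a CRISPR-Cas9 knockout of HMGA2 were on 3 further arrays, with knockout #2 on 1 array and knockout #8 on 2. MKN45, a gastric cancer line, received siRNA against SERPINH1 on 2 arrays, siSERPINH1-1 and siSERPINH1-2. HMGA2 encodes an architectural protein of chromatin, and SERPINH1 encodes a collagen chaperone of the endoplasmic reticulum. Each group thus had 2 reagents, which are the replicates (n = 2), and all values are log2 ratios of treated over mock cells unless another unit is given. The labels give the mock cells as not transfected and do not say whether they received reagent alone, so the siRNA arrays do not separate the target from transfection. Median spot signals were 21 to 24 in the green and 19.5 to 25 in the red channel, over background medians of 15 to 18 and 17 to 18. Between 41.8% and 47.7% of probes were well above background in green and between 36.0% and 53.5% in red. The low end in red was knockout #8, with 37.2% on mock B and 36.0% on mock A, against at least 47.6% on the other arrays. Its red medians of 21 and 19.5 were also the lowest. Spike-in ratios followed their design with r from 0.979 to 0.990 and slopes from 0.792 to 0.849.

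The targeted genes were measured first. At its brightest probe (A_23_P95930), HMGA2 had log2 ratios of -1.54 and -0.81 on the siHMGA2-2 arrays and -1.92 on the siHMGA2-3 array. The group mean of -1.55 (SE 0.31, n = 2 siRNAs) left 34.2% of the mock level, with a limma adjusted p of 0.0753, so HMGA2 itself did not pass. Knockout #2 had -1.34, and knockout #8 had 0.04 on mock B and -0.50 on mock A, which gave a mean of -0.78 (SE 0.31, n = 2 lines, adjusted p = 0.463), or 58.1% of the mock level. A knockout need not lower the transcript, and the edited position is not known from the labels. At the dimmer HMGA2 probes A_33_P3211078 and A_33_P3357658 the means were -0.49 and -0.55 with siHMGA2, and -0.32 and -0.18 in the knockout. In MKN45, where HMGA2 was not targeted, its log2 ratios were 0.27 and 0.38. SERPINH1 had -1.65 with siSERPINH1-1 and -2.16 with siSERPINH1-2, a mean of -1.91 (SE 0.21, n = 2 siRNAs) that left 26.6% of the mock level. In TE-8, where SERPINH1 was not targeted, its log2 ratios lay between -0.35 and 0.80. With siSERPINH1 its limma adjusted p was 0.350, in a comparison where no gene passed.

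**Figure D1:**
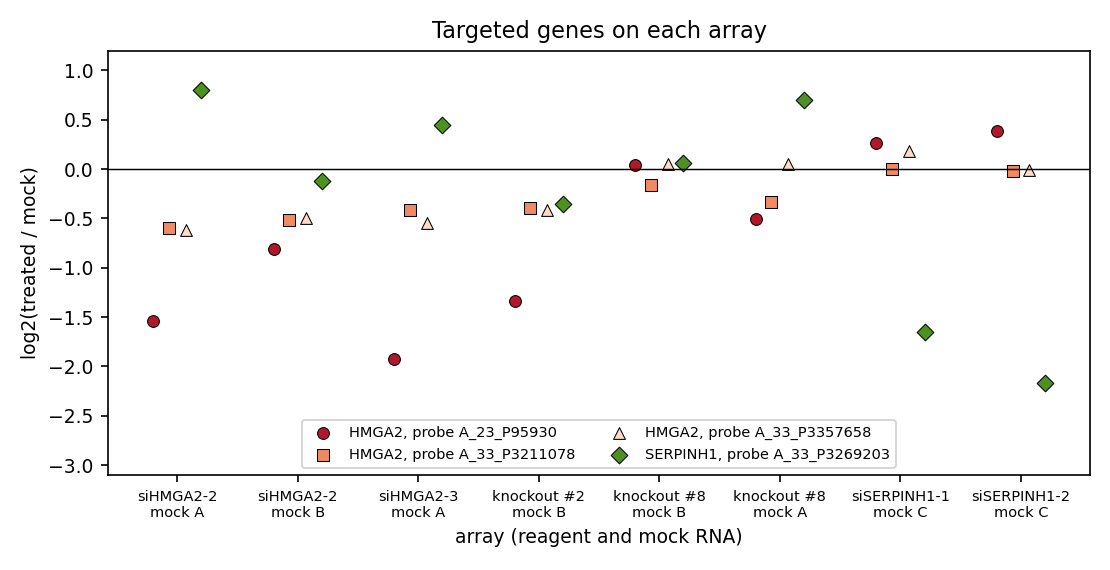
Log2 ratio of treated over mock (y axis) on each of the 8 arrays (x axis, by reagent and mock RNA) for the 3 HMGA2 probes and the SERPINH1 probe, 1 point per probe and array. HMGA2 at its brightest probe lies between -1.92 and -0.81 on the siHMGA2 arrays and at 0.04 and -0.50 on the knockout #8 arrays, and SERPINH1 lies at -1.65 and -2.16 on the MKN45 arrays.

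The siHMGA2 arrays ask which transcripts depend on HMGA2 in TE-8. KRT15, a keratin of basal squamous cells, fell by 3.11 on the log2 scale (SE 0.16, n = 2 siRNAs), or 8.66-fold, and was lower on all 3 arrays. Further genes that fell were PCLAF, a binding partner of the replication clamp (-2.13), TK1, the thymidine kinase of nucleotide salvage (-1.78), and UNG, a uracil-DNA glycosylase (-1.73). NDE1, a protein of the centrosome and mitotic spindle (-2.11), the focal adhesion gene TNS4 (-1.77), the annexin gene ANXA10 (-1.76) and the growth factor receptor gene EGFR (-1.71) also fell. Among genes that rose were MALAT1, a long noncoding RNA of the nucleus (1.95), SQSTM1, an autophagy receptor (1.70), the small nucleolar RNA gene SNORD116-19 (1.62), TMEM40 (1.58), GPRC5C (1.45), the annexin gene ANXA1 (1.43), ZCWPW1, a reader of histone methylation (1.40), and IDS, a lysosomal sulfatase (1.36). The SE of these 16 genes ranged from 0.07 to 0.24 and their limma adjusted p from 0.0344 to 0.0475.

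Over all genes, 157 of 14959 tested rose and 216 fell, a total of 373, and 108 of them changed by at least 2-fold (33 rose and 75 fell). At an unadjusted p under 0.05 there were 3703 genes, against 748 by chance. Counts by chance, here and below, take no account of the spread of the mock RNAs. Counts with each array as its own replicate, here and below, treat the 2 arrays of siHMGA2-2 and of knockout #8 as independent. The count was 12 with the processed ratios of the scanner software, where the adjusted p of the 16 genes named above, KRT15 excepted, lay between 0.0521 and 0.0745, and 0 with median centring, with the spread estimated from the TE-8 arrays alone, with the MKN45 arrays subtracted, or with the mock RNAs as their own group. It was 0 without the siHMGA2-3 array, 1645 without siHMGA2-2, and 3051 with each array as its own replicate.

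Cell division genes were lower as groups with siHMGA2. Of 31 G2/M genes tested, 31 had a mean below 0 and the list mean was -1.10 (camera adjusted p = 1.22e-12; adjusted p = 0.790 with an estimated correlation). CCNA2, a cyclin of S and G2 phase (-1.06), and the centrosomal kinase gene NEK2 (-0.69) fell, which made 2 genes over all genes tested, against 22 adjusted over the list alone. All 36 DNA replication genes had a mean below 0, with a list mean of -0.85 (camera adjusted p = 8.00e-12; adjusted p = 0.790 with an estimated correlation). Of these, 5 fell, among them TK1, GINS1 of the replicative helicase (-1.32), the cell cycle transcription factor gene E2F1 (-0.999) and CHAF1B of chromatin assembly (-0.80), against 13 adjusted over the list alone. The size of both shifts differed between the siRNAs: G2/M genes averaged -1.70 with siHMGA2-3 and -0.44 and -0.56 on the siHMGA2-2 arrays, and DNA replication genes averaged -1.39, -0.27 and -0.35. Relative to the other genes the G2/M shift of -1.08 was -0.51 without siHMGA2-3 and -1.66 without siHMGA2-2, and the DNA replication shift of -0.83 was -0.32 and -1.36, and both lists passed each time.

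Squamous basal and lineage markers were also lower with siHMGA2, with 13 of 14 below 0 and a list mean of -0.60 (camera adjusted p = 4.63e-05; adjusted p = 0.558 with an estimated correlation). KRT15 and TP63, the transcription factor of squamous basal cells (-0.77), fell, and 9 fell adjusted over the list alone. Of 15 tested genes reported downstream of HMGA2, 12 lay below 0 with a list mean of -0.37 (camera adjusted p = 0.0102; adjusted p = 0.790 with an estimated correlation). Only CCNA2, which is also a G2/M gene, fell over all genes tested, and 6 fell adjusted over the list alone; relative to the other genes this list was at -0.34, and at -0.20 without siHMGA2-3, where it still passed. Of 27 genes of the unfolded protein response, 23 lay above 0 with a list mean of 0.36 (camera adjusted p = 0.0195; adjusted p = 0.790 with an estimated correlation), while 0 passed over all genes or adjusted over the list alone and 7 were higher at an unadjusted p under 0.05 in limma. Its member of smallest p was PPP1R15A, a stress-induced phosphatase subunit (0.72, adjusted p = 0.0571). The list did not pass without the siHMGA2-2 array on mock A (0.40 relative to the other genes) or without siHMGA2-3 (0.33).

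The remaining 14 lists did not pass camera with siHMGA2, but 3 of their members did pass the test of single genes. The collagen and extracellular matrix list had a mean of 0.02 over 23 genes (camera adjusted p = 0.770), with COL1A1, a fibrillar collagen chain, at 1.35 (rose) and the laminin chain gene LAMB1 at -1.56 (fell). Gastric and intestinal lineage markers had a mean of -0.10 over 12 genes (0.720), of which the simple-epithelium keratin gene KRT8 fell by 1.06. In the other lists no member passed. Mesenchymal and EMT genes had a list mean of -0.14 (camera adjusted p 0.528), with SNAI2 at -0.46, and epithelial junction genes -0.04 (0.928), with OCLN at 0.22 (1.55 with the processed ratios), its mock signal well above background on 1 of 3 arrays. Collagen processing enzymes and chaperones had -0.10 (0.720), with FKBP10 at -0.89, cytosolic heat shock genes -0.06 (0.720), with HSPB8 at 0.75, and interferon response genes -0.08 (0.716), with IFITM1 at -1.03. The list means were 0.08 for p53 targets (0.878), with BBC3 at 1.51, -0.21 for squamous differentiation genes (0.415), with KRT13 lower by at least 1.32-fold, since its treated signal was not well above background, and -0.17 for TGF-beta and YAP response genes (0.770), with ID1 at -2.83. NF-kB and inflammatory cytokine genes had 0.11 (0.528), with TNFAIP6 at -0.38, sterol synthesis genes -0.24 (0.104), and hypoxia and glycolysis genes -0.35 (0.270), with ALDOC at -0.89. RNA interference machinery had 0.04 (0.720), with TNRC6C at 0.67. Counts adjusted over the list alone in these 14 lists were at most 4 genes on a side, for NF-kB and inflammatory cytokine genes.

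**Figure D2:**
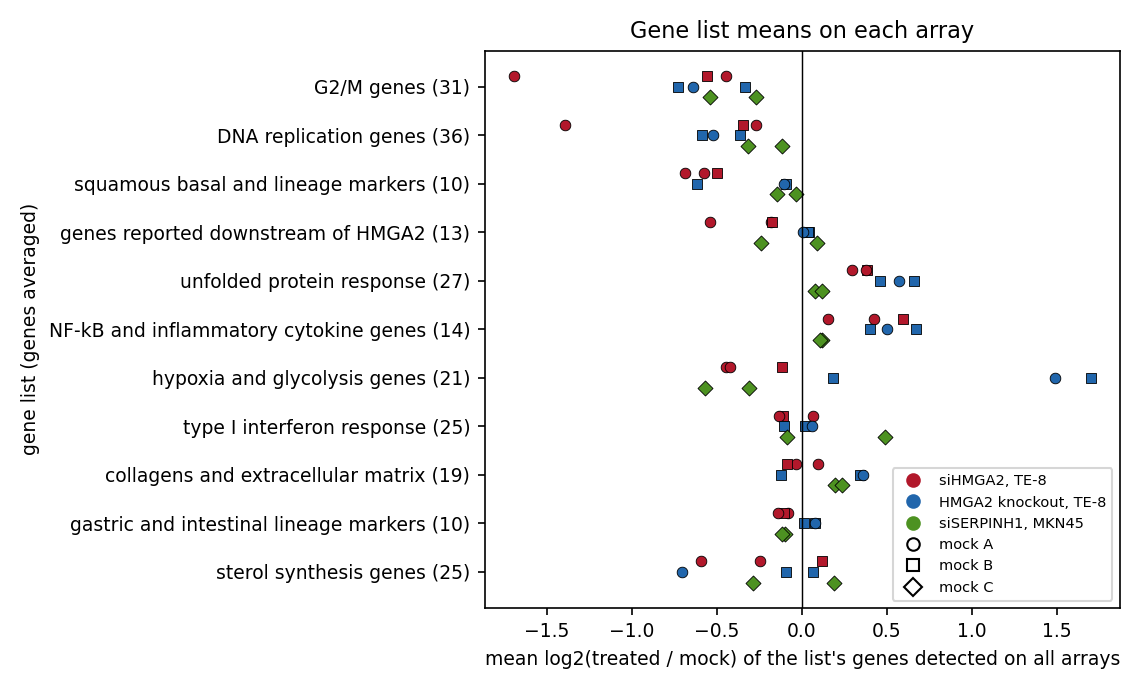
Mean log2 ratio of treated over mock (x axis) of 11 gene lists (y axis, with the number of genes detected on all 8 arrays), 1 point per array, coloured by group and shaped by mock RNA. G2/M genes lie below 0 on every array, from -1.70 to -0.27, and hypoxia and glycolysis genes lie at 1.70 and 1.49 on the knockout #8 arrays against 0.18 for knockout #2.

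The knockout arrays put the same question with the gene edited. KRT15 had a log2 ratio of -2.66 (SE 0.16, n = 2 lines) and lay between -2.97 and -2.20 on the 3 arrays, but its limma adjusted p was 0.157. PKN3, a kinase gene (-0.83), NAV2 (-0.88), the histone gene H2AC17 (-0.59), SAC3D1 (-0.62), MRPS12 of the mitochondrial ribosome (-0.60), the RNA export factor gene ALYREF (-0.59) and SNORD86 (-0.51) had the next smallest p on the lower side under the naming rule. On the higher side stood ERRFI1, a feedback inhibitor of EGFR signalling (1.99), EMP1 (0.95), the inflammation-induced hyaluronan binder gene TNFAIP6 (0.91), SNORD116-19 (0.84), the syndecan gene SDC4 (0.80), MAST4 (0.79), ZC3H12C (0.70) and the transcription factor gene MEF2A (0.68). None of these passed, with adjusted p from 0.157 to 0.296.

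With limma, 0 of 13982 genes passed in the knockout, while 1566 had an unadjusted p under 0.05, against 699 by chance. With each array as its own replicate 298 passed, a count that treats the 2 arrays of knockout #8 as independent.

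Several gene groups lay to one side in the knockout. All 36 DNA replication genes were below 0 with a list mean of -0.46 (camera adjusted p = 1.77e-09; adjusted p = 0.645 with an estimated correlation), with 5 lower adjusted over the list alone and GINS1 at -0.55. Of 31 G2/M genes 30 were below 0 with a mean of -0.51 (camera adjusted p = 1.05e-08; adjusted p = 0.645 with an estimated correlation), 0 adjusted over the list alone, and NEK2 at -0.49. All 21 hypoxia and glycolysis genes were above 0 with a mean of 0.89 (camera adjusted p = 2.74e-08; adjusted p = 0.645 with an estimated correlation) and 0 adjusted over the list alone. ANGPTL4, a hypoxia-induced secreted protein gene, was at 2.75 with an SD between the lines of 2.01. This list averaged 1.70 and 1.49 on the knockout #8 arrays and 0.18 for knockout #2. Of 27 genes of the unfolded protein response 20 were above 0 with a mean of 0.54 (camera adjusted p = 5.25e-05; adjusted p = 0.645 with an estimated correlation), 3 higher adjusted over the list alone, and the stress transcription factor gene DDIT3 at 1.43. Of 22 NF-kB and inflammatory cytokine genes 17 were above 0 with a mean of 0.60 (camera adjusted p = 0.000214; adjusted p = 0.645 with an estimated correlation), 2 higher adjusted over the list alone, TNFAIP6 among those named. Squamous basal and lineage markers had 9 of 15 below 0 and a mean of -0.24 (camera adjusted p = 0.0498; adjusted p = 0.645 with an estimated correlation), with 4 lower adjusted over the list alone.

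Genes reported downstream of HMGA2 had 8 of 15 above 0 and a mean of 0.04 in the knockout (camera adjusted p = 0.663). They belonged to 13 lists that did not pass camera there, with list means from -0.17 to 0.28 and adjusted p of at least 0.0600. Adjusted over the list alone, these lists had at most 2 genes a side. Their members of smallest p did not pass either. They were SNAI2 (0.43), the tight junction gene TJP1 (0.60), COL7A1 (0.61), LOXL2 (1.04), ISG20 (0.69), BAX (-0.50), KRT10 (0.56), GATA6 (0.46), AMOTL2 (0.55), the fatty acid synthase gene FASN (-0.82), AGO1 (0.34) and the heat shock gene HSPA1A (-2.21, with an SD between the lines of 1.66). Without knockout #8 the hypoxia and glycolysis list stood at 0.16 above the other genes, the unfolded protein response at 0.44 and the NF-kB list at 0.33, and none of the 3 passed. Without the knockout #2 array the squamous basal list stood at -0.08, and without the knockout #8 array on mock B at -0.24, and it did not pass either time. Without the knockout #2 array the hypoxia and glycolysis list stood at 1.49, and without knockout #8 the squamous basal list stood at -0.40, and both passed.

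Over both methods, genes were sought that moved one way on all 6 TE-8 arrays. KRT15 fell by 2.88 on the log2 scale (SE 0.11, n = 4 reagents, adjusted p = 0.0210), or 7.39-fold. UNG (-1.29), PCLAF (-1.29), TK1 (-1.17) and the histone variant gene H2AX (-0.97) fell, as did OLFML2A (-1.15), IGFLR1 (-1.04) and the inositol phosphatase gene IMPA2 (-1.03). MALAT1 (1.46), SQSTM1 (1.34), SNORD116-19 (1.23), ANXA1 (0.97), WASL of actin assembly (0.95), MEF2A (0.80), the kinase gene MKNK2 (0.79) and the transporter gene SLC26A11 (0.78) rose. The SE of these 16 genes ranged from 0.05 to 0.14 and their adjusted p in limma from 0.0210 to 0.0457. HMGA2 itself had -1.17 (SE 0.22, adjusted p = 0.0715). Several of the 16 genes moved the same way on both siSERPINH1 arrays, although no gene passed there. The direction of those changes was thus not seen with HMGA2 loss alone. What the arrays share in these genes was not tested here. MALAT1 (1.11 and 1.12), SQSTM1 (0.39 and 0.62), WASL (0.49 and 0.50), MKNK2 (0.40 and 0.76) and SLC26A11 (0.18 and 0.57) were higher. TK1 (-0.31 and -0.64) and H2AX (-0.26 and -0.44) were lower. IGFLR1 and SNORD116-19 did so by less, UNG and OLFML2A lay the other way, and the rest had mixed signs.

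**Figure D3:**
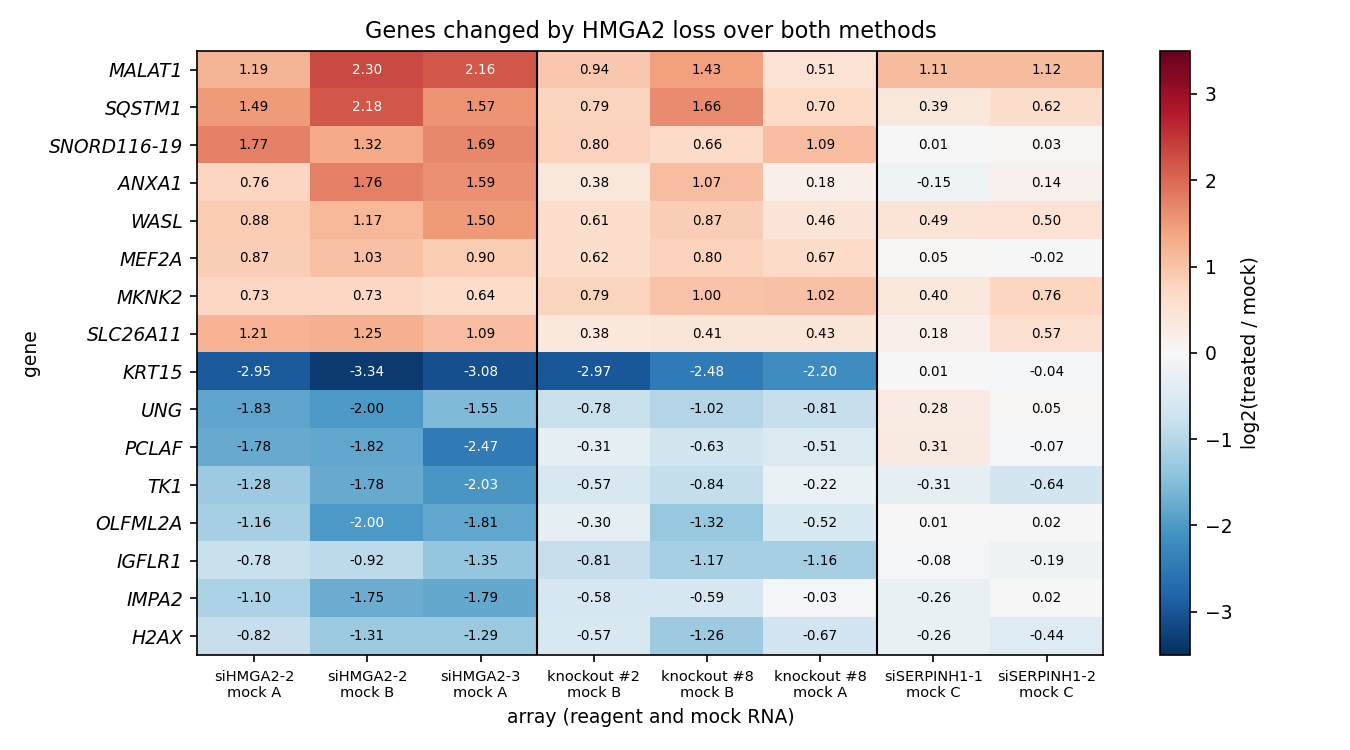
Log2 ratio of treated over mock (colour and printed value) of the 16 genes named for HMGA2 loss over both methods (y axis) on each of the 8 arrays (x axis, by reagent and mock RNA). KRT15 lies between -3.34 and -2.20 on the 6 TE-8 arrays and at 0.01 and -0.04 on the MKN45 arrays, whereas MALAT1 is above 0 on all 8 arrays.

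In all, 48 of 13889 genes rose and 74 fell, which makes 122, and 10 changed by at least 2-fold (3 rose and 7 fell). At an unadjusted p under 0.05 there were 3402 genes, against 694 by chance. The count was 9 with the processed ratios of the scanner software, and 0 with median centring, with the TE-8 arrays alone, with the MKN45 arrays subtracted, or with the mock RNAs as their own group; each array as its own replicate gave 1911. It was 1 without the knockout #2 array or without knockout #8, and 1231 without siHMGA2-2.

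Of 31 G2/M genes 31 were below 0 over both methods with a list mean of -0.80 (camera adjusted p = 6.98e-14; adjusted p = 0.697 with an estimated correlation), and 1 fell (NEK2, -0.59), against 23 adjusted over the list alone. All 36 DNA replication genes were below 0 with a mean of -0.66 (camera adjusted p = 7.87e-14; adjusted p = 0.697 with an estimated correlation). In this list 5 fell, among them TK1, GINS1 (-0.94), E2F1 (-0.82) and the cyclin gene CCNE1 (-0.72), against 14 adjusted over the list alone. Squamous basal and lineage markers had 10 of 14 below 0 and a mean of -0.42 (camera adjusted p = 0.000641; adjusted p = 0.460 with an estimated correlation). KRT15, the basal keratin gene KRT5 (-0.92) and TP63 (-0.53) fell, against 6 adjusted over the list alone; with the processed ratios of the scanner software KRT5 was at -2.90 and TP63 at -1.07, and the treated signal of KRT5 was well above background on 4 of 6 arrays. Fry gave this list an adjusted p of 0.0390. Relative to the other genes the G2/M shift of -0.79 was -0.51 and the DNA replication shift of -0.65 was -0.39 without siHMGA2-3, and both passed.

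The unfolded protein response had 21 of 27 genes above 0 over both methods and a mean of 0.45 (camera adjusted p = 0.000609; adjusted p = 0.460 with an estimated correlation), with 0 genes past the limma test, 6 higher adjusted over the list alone, 8 higher at an unadjusted p under 0.05, and PPP1R15A at 0.65. NF-kB and inflammatory cytokine genes had 19 of 22 above 0 and a mean of 0.31 (camera adjusted p = 0.00727; adjusted p = 0.697 with an estimated correlation), 1 higher adjusted over the list alone, and TNFAIP6 at 0.26; without knockout #8 the list stood at 0.22 relative to the other genes and did not pass. TNFAIP6 itself was below 0 on all siHMGA2 arrays (mean -0.38) and above 0 on all knockout arrays (mean 0.91), so its 0.26 averages opposite values. Sterol synthesis genes had 18 of 25 below 0 and a mean of -0.20 (camera adjusted p = 0.0406, or 0.979 with an estimated correlation). Adjusted over the list alone, 1 of them was lower. The sterol list averaged -0.60, -0.25 and -0.70 on the 3 arrays with mock A and 0.12, 0.07 and -0.09 on the 3 arrays with mock B. It did not pass without the siHMGA2-2 array on mock A (-0.11 relative to the other genes), the knockout #8 array on mock A (-0.12), siHMGA2-2 (-0.18) or knockout #8 (-0.09), while the value of -0.19 with all arrays became -0.30 without the knockout #2 array, -0.27 without the knockout #8 array on mock B and -0.28 without the siHMGA2-2 array on mock B, and passed each time. Genes reported downstream of HMGA2 had a mean of -0.16 over both methods (camera adjusted p = 0.197) and did not pass. They belonged to 13 lists that did not pass, with means from -0.16 to 0.27 and camera adjusted p of at least 0.160. Adjusted over the list alone, these lists had at most 3 genes a side. Their members of smallest p were ZEB1 (0.32), DSP (-0.26), COL1A1 (0.67), FKBP14 (-0.47), HSPA1A (-1.12), ISG20 (0.69), BBC3 (1.00), KRT8 (-0.67), TET1 (-0.76), AMOTL2 (0.47), STC2 (0.75), TNRC6C (0.51) and KRT13 (lower by at least 1.26-fold, with a treated signal not well above background), none of which passed.

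The likeness of the methods was measured across 13045 genes, which are not independent replicates. The mean log2 ratios of siHMGA2 and of the knockout correlated with Pearson r 0.332 and Spearman rho 0.303, with 59.5% of genes of the same sign. Simulations of unchanged groups gave a mean r of -0.187 and a covariance of -0.00357, against 0.0356 observed. They placed the unchanged cells midway between mock A and mock B, which makes the simulated value negative by construction. Deviations that each mock carries by itself were left out and would raise r. The simulation thus cannot say how much of the correlation the shared mocks give. With only arrays that share no mock, r was 0.265 for siHMGA2 on mock A against the knockout on mock B, and 0.05 for siHMGA2-2 on mock B against knockout #8 on mock A. For scale between single arrays, siHMGA2-2 and siHMGA2-3 correlated with r 0.320 on the same mock and 0.315 on different mocks. Knockouts #2 and #8 correlated with 0.371 on the same mock and 0.190 on different mocks. The 2 arrays of siHMGA2-2 and of knockout #8 correlated with 0.838 and 0.832. Single arrays are not averaged over reagents, so these values are not like those of the group means. Across 22459 probes, single siHMGA2 and knockout arrays on different mocks correlated with r from 0.04 to 0.24. On the same mock this was 0.13 to 0.39. Across cell lines, the group means of siHMGA2 in TE-8 and siSERPINH1 in MKN45 correlated with r 0.323 (rho 0.314). These groups share neither target nor mock. The group means of the knockout and siSERPINH1 correlated with r 0.267 (rho 0.282).

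Of the 155 genes that rose with siHMGA2 and were tested in both comparisons, 52 were higher in the knockout at an unadjusted p under 0.05, against 8.07 expected from independent comparisons. Of the 216 that fell, 83 were lower, against 13.0 expected. The arrays of both comparisons share mock RNAs and a spread estimate, so these comparisons are not independent.

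**Figure D4:**
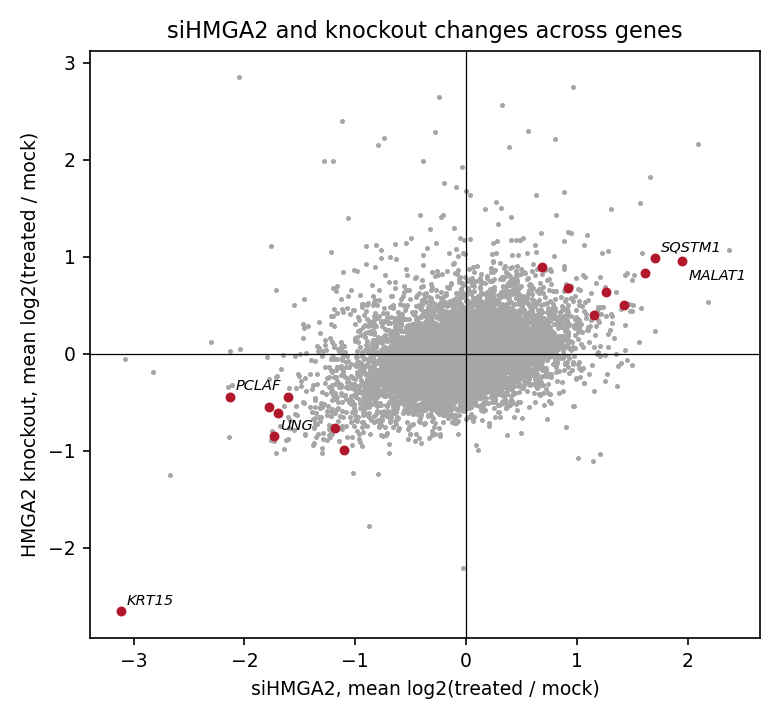
Mean log2 ratio in siHMGA2 (x axis) and in the HMGA2 knockout (y axis), 1 point for each of 13889 genes tested in both, with the 16 genes named over both methods in red. KRT15 lies at -3.11 and -2.66, and MALAT1 and SQSTM1 lie above 0 on both axes.

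The difference of siHMGA2 and knockout was tested directly. The mocks were not balanced in it, since siHMGA2-3 was on mock A only and knockout #2 on mock B only. A difference between the mock RNAs is thus part of this contrast. The hypoxia and glycolysis list was higher in mock A than in mock B by a mean of 0.27, with 18 of 21 genes higher. By limma 0 of 13889 genes differed, with a smallest adjusted p of 0.194, while 1941 had an unadjusted p under 0.05 against 694 by chance, and 815 passed with each array as its own replicate. Among the genes of smallest p on the higher side were SCARNA20, a small Cajal body RNA gene (1.51), GPRC5C (1.51), ZCWPW1 (2.83-fold) and the chloride transporter gene CLCN6 (1.00). On the lower side they were CREB3L2 (-1.86), CORO1C of the actin cytoskeleton (-1.42), TNFAIP6 (-1.30), CD52 (-1.26) and ELFN2 (-1.21). Hypoxia and glycolysis genes were lower with siHMGA2 than in the knockout by a mean of -1.24 (camera adjusted p = 4.68e-06; adjusted p = 0.809 with an estimated correlation), with 20 of 21 genes below 0. G2/M genes differed by -0.59 (camera adjusted p = 3.11e-05; adjusted p = 0.810 with an estimated correlation) and DNA replication genes by -0.39 (camera adjusted p = 0.00115; adjusted p = 0.823 with an estimated correlation). Relative to the other genes the hypoxia difference of -1.21 was -0.49 without knockout #8 and -1.93 without knockout #2, and without the siHMGA2-3 array the G2/M and DNA replication differences were 0.01 and 0.15. Genes reported downstream of HMGA2 differed by -0.40 and squamous basal and lineage markers by -0.37 (camera adjusted p = 0.00183 for both; adjusted p = 0.809 with an estimated correlation). Relative to the other genes the downstream list was at -0.37, and at -0.23 without siHMGA2-3, and the squamous basal list was at -0.34, and at -0.18 without knockout #8, where it did not pass. Adjusted over the list alone, 2 DNA replication genes and 1 gene reported downstream of HMGA2 were lower, and 0 in the other 3 lists. The other 14 lists had camera adjusted p of at least 0.119 and at most 2 genes a side adjusted over the list alone.

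The siSERPINH1 arrays ask which transcripts depend on SERPINH1 in MKN45. C2CD4A and C2CD4B, neighbouring genes induced by inflammatory cytokines, had log2 ratios of 1.59 (SE 0.14) and 1.03 (SE 0.06, n = 2 siRNAs). MALAT1 (1.11), the exchange factor gene VAV3 (0.97), PELI1, a ubiquitin ligase gene (0.92), the small Cajal body RNA gene SCARNA18 (0.87), the protease gene CTSF (0.76) and CATSPERZ (0.54) were also among the smallest p on the higher side. On the lower side stood PHGR1 of the gastrointestinal epithelium (-1.003), the gastric protease gene CTSE (-0.83), LGALS4, an intestinal galectin gene (-0.74), MYO1A of the brush border (-0.59), SLCO2B1 (-0.61), EPS8L3 (-0.60), KRT83 (-0.58) and VILL (-0.56). None of these passed. By limma 0 of 14749 genes passed, with a smallest adjusted p of 0.321, while 1104 had an unadjusted p under 0.05 against 737 by chance, and 17 passed with each array as its own replicate.

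Gastric and intestinal lineage markers were lower in siSERPINH1 cells as a group, with 18 of 24 below 0 and a list mean of -0.24 (camera adjusted p = 2.54e-06; adjusted p = 0.203 with an estimated correlation). In limma 0 of them passed over all genes and 6 were lower adjusted over the list alone, and fry gave an adjusted p of 0.00445. G2/M genes had 30 of 31 below 0 and a mean of -0.41 (camera adjusted p = 3.24e-09; adjusted p = 0.833 with an estimated correlation), with NEK2 at -0.33. DNA replication genes had 34 of 36 below 0 and a mean of -0.22 (camera adjusted p = 8.99e-05; adjusted p = 0.833 with an estimated correlation), with RFC3 at -0.49. Hypoxia and glycolysis genes had 21 of 22 below 0 and a mean of -0.42 (camera adjusted p = 0.000183; adjusted p = 0.833 with an estimated correlation), with ALDOC at -0.53. Collagen and extracellular matrix genes had 19 of 22 above 0 and a mean of 0.20 (camera adjusted p = 0.0111; adjusted p = 0.533 with an estimated correlation), with LAMB1 at 0.55. Interferon response genes had 23 of 30 above 0 and a mean of 0.19 (camera adjusted p = 0.00118; adjusted p = 0.833 with an estimated correlation), with STAT2 at 0.42. Adjusted over the list alone, 0 genes passed in these last 5 lists. The interferon list averaged 0.49 with siSERPINH1-1 and -0.09 with siSERPINH1-2. Without siSERPINH1-1 it stood at -0.08 relative to other genes and did not pass, and without siSERPINH1-2 at 0.37. Without siSERPINH1-2 the DNA replication list stood at -0.15 and passed, and the collagen and extracellular matrix list stood at 0.16 and did not pass.

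Collagen processing enzymes and chaperones, the list closest to the function of SERPINH1, had a mean of 0.08 over 23 genes in siSERPINH1 cells (camera adjusted p = 0.659), with P3H3 at 0.79, and the unfolded protein response a mean of 0.10 over 27 genes (0.562), with CANX at 0.30. These belonged to 13 lists that did not pass, with means from -0.08 to 0.12 and camera adjusted p of at least 0.403, and adjusted over the list alone 1 gene in all, SOX2. Members of smallest p in other lists were ACTA2 (0.33), OVOL1 (-0.23), CHORDC1 (-0.17), TP53INP1 (0.30), SPRR1A (0.52), SOX2 (0.60), CCNA2 (-0.38), BAMBI (0.97), PTGS2 (0.87) and TNRC6C (0.54). With median centring OVOL1 was at 0.03 and CHORDC1 at 0.16, under a scaling that moved the median of tested genes to 0.19.

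Among lists that did not pass camera, the mean, the median and the direction of the test were not all of one sign in some cases. These were the interferon list with siHMGA2, in the knockout and in the difference, epithelial junction genes in the knockout and over both methods, and gastric and intestinal lineage markers in the knockout and over both methods. The others were heat shock and squamous differentiation genes in the knockout, TGF-beta and YAP response genes over both methods, and squamous basal markers in siSERPINH1 cells.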

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

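The tests of siRNA transfection, of the mock difference for HMGA2, and of mock RNA on the knockout #8 arrays were chosen after the results were seen. The splits of the TE-8 arrays were added after the data were seen, with their prediction written before their result.

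Camera tested the difference between siHMGA2 and knockout itself for gene lists, and it passed for 5: G2/M genes (-0.59), DNA replication genes (-0.39), squamous basal and lineage markers (-0.37), genes reported downstream of HMGA2 (-0.40) and hypoxia and glycolysis genes (-1.24), all lower with siHMGA2 than in the knockout. None of these passed with an estimated correlation. Relative to the other genes the G2/M and DNA replication differences were 0.01 and 0.15 without siHMGA2-3, the hypoxia difference was -0.49 without knockout #8 and -1.93 without knockout #2, and the squamous basal difference was -0.18 without knockout #8 and did not pass. The downstream difference was -0.23 without siHMGA2-3. Among named genes, 12 had one sign on all siHMGA2 arrays and the opposite sign on all knockout arrays. The difference was -2.87 for ANXA10, -2.06 for LAMB1, -1.86 for CREB3L2, -1.42 for CORO1C, -1.30 for TNFAIP6, -1.26 for CD52, -1.21 for ELFN2, -0.89 for SNAI2, -0.78 for TJP1, 1.51 for GPRC5C, 1.51 for SCARNA20 and 1.05 for SCARNA18. The limma test of the difference did not pass for these genes. The difference also carries the mock RNAs, since siHMGA2-3 was on mock A only and knockout #2 on mock B only. Of 13889 genes, 3570 had one sign within each group, and the signs were opposite for 1009 of them and equal for 2561. With each array as its own replicate, 815 genes differed between siHMGA2 and knockout, and the highest count among other splits of the 6 arrays into 3 and 3 was 156. The real split was the 1 split with as many genes, but 10 splits are too few to reach a share under 0.05. Besides, siHMGA2-2 and knockout #8 were each on 2 arrays, and the 8 splits that part arrays of 1 RNA called 0 genes, so they say little on chance.

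Probes without a gene name were outside the comparisons of genes. Of 7866 such probes tested with siHMGA2, 4 passed, and all 4 were higher than in the mock.

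The log2 ratios of siHMGA2 in TE-8 and of siSERPINH1 in MKN45 correlated across genes with r 0.323. A gene-specific dye effect, which would belong to a probe sequence, was tested on 3210 genes with several probes: the covariance between different probes over that at the same probe, relative to a contrast free of dye effects, was 0.966 (bootstrap 95% interval 0.845 to 1.1), which argues against a dye effect as the whole cause, although the positions of the probes on the transcripts were not compared. A response to siRNA transfection stays open: relative to siHMGA2, the knockout had 0.827 of the r and 0.562 of the covariance with siSERPINH1, but 0.506 and 0.344 with siSERPINH1-2 alone, against 1.38 and 0.937 with siSERPINH1-1. A slower cell cycle in treated and knockout cells is a candidate explanation that was not tested. Growth state or handling of the mock cells stays open too, because every ratio was taken against mock cells.

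Sterol synthesis genes moved with the mock RNA on the array. The difference of mock A and mock B in this list was 0.72 from the siHMGA2-2 arrays and 0.61 from the knockout #8 arrays, where the mock B arrays had the higher ratios. The shift lay mostly in the mock channel: the list moved by 0.01 and -0.14 in the channel of the treated RNA, at most 0.236 of the shift of the ratio, just under the limit of 0.25 set for a difference between the mock RNAs. Dye normalization as the whole cause is argued against, since with median centring or the processed ratios at least 1.41 times the difference was left. The size of this share is not interpreted. These list means were not taken relative to the other genes, and the processed ratios carry their own dye normalization. What set the mocks apart is not known from the labels, and no biological explanation tied to HMGA2 was tested.

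HMGA2 transcript in knockout #8 was at 0.04 on mock B and at -0.50 on mock A. At this brightest probe it moved with the mock, since the log2 ratio was higher on mock B than on mock A by 0.72 for siHMGA2-2 and by 0.54 for knockout #8. A higher HMGA2 level in mock A than in mock B thus accounts for part of the value on mock B at this probe. The dimmer probes moved less. Knockout #8 was at -0.16 on mock B and -0.33 on mock A at A_33_P3211078, and at 0.048 and 0.053 at A_33_P3357658. For siHMGA2-2 these were -0.52 and -0.60, and -0.50 and -0.62. Mock RNA in place of knockout RNA is argued against: the SD over genes of the ratios of knockout #8 on mock B was 1.60 times that of the mock difference, and 208 genes differed by at least 2-fold on both of its arrays. An edit that leaves the transcript stable could give what remains, as could a partly edited line, and neither can be read from a probe.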

How the results depend on the processing

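The alternative with mock RNAs as their own group, the splits of arrays, and list shifts under median centring and offset 10 were chosen after seeing the data. No paired analysis was possible because the shared replicate numbers name different siRNAs and knockout lines in different cells. The TE-8 arrays are tied by their mock RNAs instead, which the fit with mock RNAs as their own group uses. All arrays came from 1 slide and 1 scan, so a block for slide or scan could not be run. Signals close to background limit the dim genes: without the filter on dim probes the siHMGA2 count was 227.

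The siHMGA2 count of 373 (157 rose) was 12 with the processed ratios and with the deposited ratios (5 shared), 0 with median centring, 464 with offset 10 (144 rose, 320 fell), 583 with an intensity trend (270 shared), 0 with the TE-8 arrays alone, 3051 with each array as its own replicate, 193 with the first array of each reagent, 0 with the MKN45 arrays subtracted, and 0 with mock RNAs as their own group. It was 1603 at an adjusted p under 0.1 and 0 under 0.01. The count over both methods (122) was 9, 9, 0, 293, 239, 0, 1911, 45, 0 and 0 under these alternatives in that order, 996 under 0.1 and 0 under 0.01. The knockout count of 0 was 1 with offset 10, 2 with an intensity trend and 298 with each array as its own replicate; siSERPINH1 gave 1 and 17 under the last 2, and the difference of the methods 1 and 815. The fit with the TE-8 arrays alone lost arrays and the spread of the MKN45 arrays at once, and these were not told apart. The cause was not tested for any of these settings.

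Leaving out arrays or reagents gave 0 to 1645 genes for siHMGA2 (0 without siHMGA2-3, 1645 without siHMGA2-2), 1 to 1231 over both methods (1 without knockout #2, 1 without knockout #8, 24 without the knockout #8 array on mock B and 221 without that on mock A, 249 without siHMGA2-3, 46 without the siHMGA2-2 array on mock B, 1231 without siHMGA2-2), 0 to 0 for the knockout and siSERPINH1, and 0 to 2 for the difference (2 without the siHMGA2-2 array on mock B). A lone reagent was assumed to vary like the other groups. HMGA2 with siHMGA2 ranged from -1.92 to -1.17, in the knockout from -1.34 to -0.23, and SERPINH1 from -2.16 to -1.65. HMGA2 with siHMGA2 passed with an intensity trend (-1.55) and with each array as its own replicate (-1.42). The correlation of siHMGA2 and knockout (0.332) was 0.216 with median centring, 0.265 with no shared mock and 0.245 to 0.369 with an array or reagent left out (0.245 without knockout #2). That of siHMGA2 and siSERPINH1 (0.323) was 0.378 with median centring and 0.205 to 0.337 (0.205 without siSERPINH1-2).

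Median centring moved the median of tested genes to 0.15 for siHMGA2, -0.09 for the knockout, 0.19 for siSERPINH1 and 0.28 for the difference, so list shifts were taken relative to the other genes. Of 28 list results past the threshold, 27 kept direction and threshold with the processed ratios, 27 with offset 10 and 27 with median centring, 0 kept the threshold with an estimated correlation and 2 with fry. The cases lost were the sterol list over both methods (-0.16 with the processed ratios, -0.20 with offset 10) and squamous basal markers in the difference (-0.28 with median centring). With arrays or reagents left out, 127 list values kept both, 14 missed the threshold and 3 reversed: the interferon list in siSERPINH1 (-0.078 without siSERPINH1-1, 0.37 without siSERPINH1-2), and in the difference G2/M (0.012) and DNA replication (0.15) genes without siHMGA2-3, with -1.13 and -0.88 without siHMGA2-2 as the other end. The 14 were the unfolded protein response with siHMGA2 (0.40 without the siHMGA2-2 array on mock A, 0.33 without siHMGA2-3) and in the knockout (0.44 without knockout #8), squamous basal markers in the knockout (-0.08 without #2, -0.24 without the #8 array on mock B) and in the difference (-0.18 without #8), NF-kB genes in the knockout (0.33 without #8) and over both methods (0.22), hypoxia genes in the knockout (0.16 without #8), the sterol list (-0.11 without the siHMGA2-2 array on mock A, -0.12 without the #8 array on mock A, -0.18 without siHMGA2-2, -0.09 without #8, but -0.30 and passing without #2) and collagens (0.16 without siSERPINH1-2).

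Of 152 named gene values, 6 reversed: with the other cell line subtracted TNRC6C over both methods (-0.032) and MALAT1 (-0.34), NEK2 (0.26) and CCNA2 (0.39) in siSERPINH1, and with median centring OVOL1 (0.029) and CHORDC1 (0.16) there. Of the 47 that passed, 4 still passed with the processed ratios, 47 with offset 10 and 0 with median centring, and with arrays or reagents left out 157 of their 276 values passed and 119 did not. Of the others, 1 passed with the processed ratios. The cause was not tested.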

Other observations

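The test of small nucleolar and Cajal body RNAs as a class was set before its result was seen, and probes without a gene name were looked at after the data were seen.

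Noncoding RNAs of the nucleus recurred among the named genes, in both directions. SNORD116-19 rose over both HMGA2 methods (1.23) and stood at 0.01 and 0.03 on the MKN45 arrays. SNORD86 lay below 0 on all 6 TE-8 arrays, from -0.66 to -0.46, and SCARNA18 and SCARNA20 lay above 0 on the siHMGA2 and siSERPINH1 arrays and below 0 on the 3 knockout arrays. MALAT1, a long noncoding RNA, was above 0 on all 8 arrays, from 0.51 to 2.30, with the reservation that no array carried the dyes the other way round. Over 205 detected snoRNA and scaRNA genes, the median exceeded that of protein-coding genes of like brightness on 7 of 8 arrays. The differences were 0.29 on mock A and 0.11 on mock B for siHMGA2-2, and 0.14 for siHMGA2-3 on mock A. They were 0.12 and 0.25 on the siSERPINH1 arrays. In the knockout they were 0.06 on mock A and -0.02 on mock B for #8, and 0.01 for #2 on mock B. For siHMGA2-2 and knockout #8 the value was thus higher on mock A than on mock B. A rise of this RNA class was set to need all 8 arrays, and 5 or fewer would have argued against it, so the 7 found leave it open. The larger values all came from cells that received siRNA, and the labels give their mocks as not transfected without saying whether they received reagent alone.

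Probes without a gene name gave 50 passing of 5894 tested over both HMGA2 methods, of which 21 were higher than in the mock. In limma 0 passed in the knockout, where 712 had an unadjusted p under 0.05, and 0 in siSERPINH1 cells, where 775 did.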
